A study of Tetrahymena thermophila with 6 samples.

How the data were processed

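Per the labels' protocols, total RNA was isolated on RNeasy columns with DNase digestion after storage in RNAlater, and 10 ug of it went into each Illumina library. The 6 libraries fall into 3 groups of 2: cells of strain CU428 starved for 43 hours, CU428 cells starved for 43 hours and then returned to 2% PPYS medium for 2 hours, and a mixture of strains CU428 and CU427, of different mating types, starved for 19 hours, mated for 24 hours and then returned to the same medium for 2 hours. The design text of the series gives 24 hours of starvation for the non-mating refed control, whereas the sample titles and protocols give 43 hours. The libraries of each group are the same under either reading. With 24 hours, however, the comparison of refed with starved cells would mix refeeding with a difference in starvation time. The timing of the refed control against the mated cells would change as well. Strain CU427 entered the mated libraries only, so strain and mating were not separable in these comparisons. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

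The deposited table holds estimated counts per gene, 1 column per library, not normalized. Trimmomatic, HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build, the annotation, the strand setting and the step that turned StringTie output into whole numbers are not given in the sources used here. A value of 1 was rarer than a value of 3 in every library (72 against 317 genes in starved library A), which is not how tallies of single reads fall, so the deposited values were treated as estimated (expected) counts that had already been rounded to whole numbers, and no further rounding was needed. Counting error was computed as if 1 unit were 1 read and is therefore approximate. Reads shared between near-identical gene copies, and reads of overlapping or antisense genes, cannot be told apart in such a table. The column names give a group and a letter, A or B, and the letters are not tied to the replicate numbers of the labels, so libraries are named here by group and letter.

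The table lists 26259 genes. Of these, 25340 carry locus tags and 919 carry numbers with the prefix g. All 25340 locus tags matched the reference table of RefSeq genes (assembly JCVI-TTA1-2.2) and none of the g-numbered models did. In that table the symbols only repeat the locus tags: 0 genes had another symbol, and the deposited table pairs no gene with a name. The 38 gene lists fixed before the data were examined (ribosomal proteins, histones, replication, small RNA pathway, ciliary proteins and others) were defined by patterns in gene names, and 0 of the 38 patterns matched a gene. The lists were therefore not tested, and genes are given by identifier. The reference table was used only for gene lengths and for which genes neighbour each other, because the build used by the submitters is not stated.

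Library totals ran from 105370464 (starved A) to 128979868 (mated, refed A). Within a library, 1 count corresponded to between 0.0060 and 0.0140 CPM (counts scaled to a common library total), and a gene at 0 counts was compatible with up to 3 counts, or 0.0179 to 0.0419 CPM. These floors, and the 95% exact binomial intervals given for ratios of counts, cover counting error only.

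CPM were computed from the deposited counts with library sizes scaled by the trimmed mean of M values (TMM). TMM factors were 1.19 and 1.26 in the starved libraries, 0.746 and 0.623 in the refed libraries and 1.30 and 1.11 in the mated libraries. After filterByExpr by group (minimum count 10), 22945 genes were tested, 22429 with locus tags and 516 with g numbers, and 3314 were removed. Differences were tested with edgeR (version 4.0.16, R 4.3.3) by quasi-likelihood F-tests in 1 fit of all 6 libraries with group means and no covariates, each comparison being a contrast, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The fit had 3 residual degrees of freedom, 3.88 prior degrees of freedom and a common biological coefficient of variation of 28.1%. Log2 changes of single genes are edgeR's fitted values with its default prior count, and their standard errors were derived from the F statistic. Medians, correlations, covariances, runs of genes and the plot of change against abundance use differences of mean log2 CPM with a prior count of 2. Abundance classes are by the mean CPM of the 4 libraries compared, in which both groups weigh the same. Where all libraries of a group were at 0, the fold is given as a lower bound against 3 counts in each library.

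The rule for single genes, fixed before the data were examined, took from each comparison the 2 largest rises and the 2 largest falls among genes past the threshold, with a mean of at least 10 CPM over the 4 libraries compared and no overlap between the libraries of the 2 groups. Chance alone separates 2 libraries from 2 often, so this last criterion is a filter and not a test. TTHERM_00655890, the most abundant gene of the starved libraries, was chosen after its values were seen.

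The procedure was tested on simulated data drawn from the means and sizes of the real libraries with 50 genes changed at each of 4 fold sizes. The changed genes had a mean of at least 1 CPM and went up or down at random. Scarcer genes and a shift in the composition of the libraries were therefore not covered. Far fewer genes were changed than were called in the data, where 33.9% to 62.0% of the genes tested were called. With few changed genes the Benjamini-Hochberg adjustment is stricter, so the recovery below does not carry over to the real comparisons. In the data the 3730 genes called lower after mating had a median log2 difference of -1.01. For the mated against refed comparison it recovered 1 of 50 genes changed 2-fold, 33 of 50 changed 4-fold, 48 of 50 changed 8-fold and 50 of 50 changed 16-fold, with 11 false calls among the 22518 genes tested. For refeeding it recovered 2, 36, 45 and 50 of 50, with 9 false calls among 22502, and for mated against starved cells 13, 40, 47 and 50 of 50, with 9 false calls among 22483.

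Alternatives were DESeq2 size factors within the edgeR fit, library size without scaling factors, no filter except genes at 0 everywhere, at least 10 CPM in at least 2 libraries, DESeq2 (1.42.0), limma-voom (limma 3.58.1), only the 4 libraries compared, glmTreat against a 2-fold change, and each library left out in turn. All alternatives for genes counted only in mated cells and for neighbouring genes, library totals without the most abundant gene, and the letter of the column as a replicate block were added after the data were examined. The comparisons share libraries, so overlaps between them are given beside 20 simulated data sets of unchanged groups and beside the overlap of independent lists. Changes of neighbouring genes were compared with 1000 shuffles of gene positions. The 2 libraries of each group differed by far more than sampling noise (chi-square per degree of freedom 227, 89.9 and 136.5 for starved, refed and mated cells), so none was taken as a copy of another; this does not show that they came from separate cultures.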

Results

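RNA was sequenced from Tetrahymena thermophila, a ciliate that keeps a germline micronucleus and a somatic macronucleus in the same cell. Starved cells of different mating types pair and conjugate, after which a new macronucleus develops and its DNA is amplified. The samples covered 3 states with 2 libraries each. The first was starvation for 43 hours and the second, by the titles and protocols, the same starvation with 2 hours of refeeding. The third was starvation for 19 hours, a mating period of 24 hours and 2 hours of refeeding. The series' design text places the mated, refed cells in a phase of endoreplication and the non-mating refed cells in early S phase of the vegetative cycle. Total counts were 105370464 and 107369845 in the starved libraries, 117448570 and 114883120 in the refed libraries and 128979868 and 124815955 in the mated libraries. No gene has a name in the sources used here, so genes are given by identifier and described in groups defined by how they responded.

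The 3 states differed far more than the libraries within them. Counts were found for more genes in mated, refed cells (24312 ± 591, SD, n = 2) than in starved cells (22977 ± 17.7) or refed cells (21529 ± 417). In starved cells a single gene, TTHERM_00655890, took 28.6% ± 1.03 of all counts (SD, n = 2), against 0.0135% ± 0.0066 in refed cells and 0.0835% ± 0.0020 in mated, refed cells. As few as 67 and 74 genes made up 50% of the counts in the starved libraries, against 167 and 143 genes in the refed libraries and 266 and 236 in the mated libraries. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.971, 0.978 and 0.977 within the starved, refed and mated groups, 0.898 to 0.917 between refed and mated libraries, and 0.701 to 0.760 between starved libraries and the others. The first principal component held 66.3% of the variance and the second 25.5%.

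Refeeding for 2 hours changed most of the measured transcriptome of non-mating cells. This comparison sets refed against starved cells that had not mated, with the same time of starvation by the titles and protocols but not by the design text. Of 22945 genes tested, 6594 were higher and 7621 lower in refed cells, and 4597 and 4789 passed the stricter test against a 2-fold change. Genes that rose made up 27.6% ± 1.23 of the counts of tested genes in starved cells and 88.7% ± 0.90 in refed cells (SD, n = 2), while genes that fell went from 59.0% ± 1.75 to 3.70% ± 0.34. By the mean of the 4 libraries compared, 149 of the 178 genes over 1000 CPM were higher in refed cells and 19 lower, and of the genes between 100 and 1000 CPM 822 were higher and 146 lower; under library size alone these counts were 146 and 23, and 733 and 228. Between 10 and 100 CPM the balance turned with the scaling, from 3116 higher and 1950 lower under TMM to 2103 and 3154 under library size alone. Between 1 and 10 CPM 1889 were higher and 3861 lower, and under 1 CPM 618 and 1645, against 968 and 5356, and 357 and 2300, under library size alone. Longer genes tended to change downward on refeeding, with Spearman's rho = -0.18 between change and gene length. It was -0.22 for mated against starved cells and -0.03 for mated against refed cells, and the source was not tested.

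The largest rises under the fixed rule were those of TTHERM_00559800 and TTHERM_00011160. TTHERM_00559800 had 2 and 0 counts in the starved libraries and 52.3 ± 25.8 CPM in refed cells (SD, n = 2), a ratio of 6567 with a 95% exact counting interval from 1817 to 54238 (edgeR adjusted p = 4.7e-05). Without starved library A, which held both counts, it was at least 2362-fold higher, and without starved library B the ratio was 3149. TTHERM_00011160 rose from 0.120 ± 0.045 to 467 ± 32.7 CPM, a log2 change of 11.92 with an SE of 0.43 (edgeR adjusted p = 1.52e-05). Among the falls, TTHERM_00042670 went from 86.7 ± 5.36 CPM to 0 counts in both refed libraries, at least 2277-fold lower (edgeR adjusted p = 5.39e-05), and TTHERM_00011230 from 39.1 ± 0.76 CPM to 0 counts, at least 1028-fold lower (edgeR adjusted p = 4.13e-05). TTHERM_00655890, singled out after its values were seen, fell by 10.25 on the log2 scale (SE 0.54, edgeR adjusted p = 1.89e-05). In all, 1053 genes had counts in both starved libraries and 0 in both refed libraries, and 201 genes the reverse. The split between rises and falls rested on the scaling: with library size alone, 4307 genes were higher and 11061 lower, and with totals that leave out the most abundant gene 3480 were higher and 13400 lower, and 253 of the 6594 rises were called falls. All 7621 falls and 4307 of the 6594 rises kept their call under library size alone, which moved the median log2 change of all genes from -0.208 to -1.0008.

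**Figure D1:**
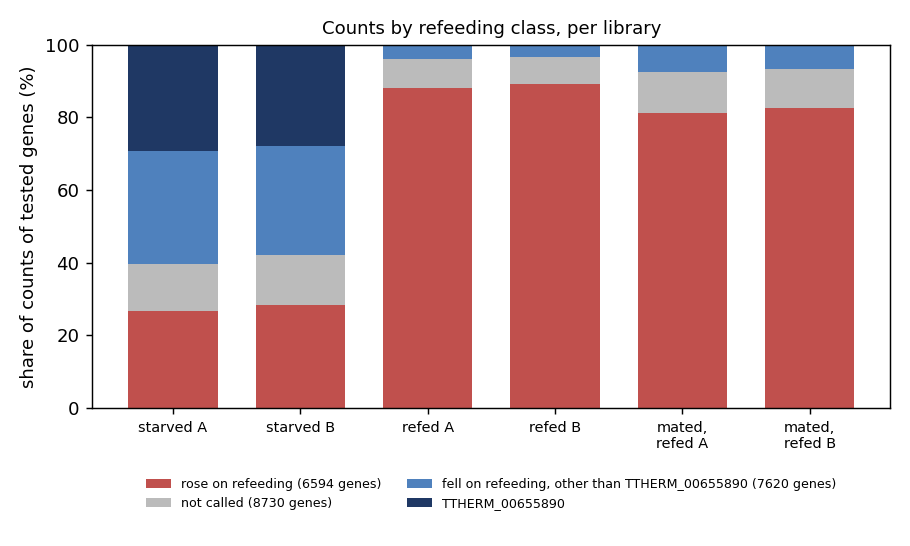
Stacked bars give, for each of the 6 libraries, the percentage of the counts of tested genes that came from genes that rose on refeeding, fell on refeeding, or were called neither way in the comparison of refed with starved cells; TTHERM_00655890, which fell, is drawn apart. Genes that rose held 27.6% of counts in starved cells, 88.7% in refed cells and 81.8% in mated, refed cells (means, n = 2), with the classes set by TMM scaling; under library size alone 4307 of the 6594 rises were still called.

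Mated, refed cells differed from non-mating refed cells in 7776 of the 22945 genes. This is the comparison named in the series' design text, of cells refed after mating with refed cells that had not mated. Of these genes, 4046 were higher and 3730 lower after mating, a split that rested on the scaling. The majority turned with the scaling between 10 and 1000 CPM. It kept its direction in the other abundance classes, although the counts moved in every class. Of 6507 genes under 1 CPM, by the mean of the 4 libraries compared, 1437 were higher and 111 lower, and under library size alone 2180 and 18. Between 1 and 10 CPM, 1959 were higher and 918 lower under TMM, against 3782 and 73 under library size alone, and between 10 and 100 CPM 611 were higher and 1857 lower, against 1772 and 91. Between 100 and 1000 CPM, 39 were higher and 698 lower under TMM, but 125 higher and 52 lower under library size alone. Of 199 genes over 1000 CPM, 146 were lower under TMM, and under library size alone 22 were lower and 3 higher. Genes higher after mating accounted for 0.890% ± 0.176 of the counts of tested genes in refed cells and 5.95% ± 0.148 in mated, refed cells (SD, n = 2), and genes lower after mating for 65.7% ± 1.17 and 53.3% ± 0.05. Among the 4046 higher genes, 812 had 0 counts in both refed libraries, and among the 3730 lower genes 12 had 0 counts in both mated libraries.

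Under the fixed rule the largest rises were those of TTHERM_00237610 and TTHERM_00189440, which had 0 counts in all 4 non-mating libraries. TTHERM_00237610 was at 120 CPM in mated library A and 20.1 CPM in B, at least 1835-fold above refed cells (edgeR adjusted p = 0.00846), or at least 527-fold by library B alone and 3142-fold by A alone. TTHERM_00189440 was at 115 and 7.87 CPM, at least 1620-fold above refed cells (edgeR adjusted p = 0.0161), a call lost with limma-voom (adjusted p = 0.122) and without refed library B (adjusted p = 0.0564); by mated library B alone it was at least 207-fold higher and by A alone at least 3032-fold. The lower genes under the rule were g6052, at 29.9 ± 30.8 CPM in refed and 2.00 ± 0.11 CPM in mated cells (SD, n = 2; log2 change -3.90, SE 0.79, edgeR adjusted p = 0.0144), and TTHERM_00264680, at 378.5 ± 247 and 26.1 ± 25.4 CPM (log2 change -3.86, SE 0.99, edgeR adjusted p = 0.0265). For g6052 the refed libraries stood at 51.6 and 8.13 CPM, its log2 change was -2.02 without refed library A and -4.69 without refed library B, and its call was lost without mated library A (adjusted p = 0.0989) or B (adjusted p = 0.0774). For TTHERM_00264680 the mated libraries stood at 8.09 and 44.1 CPM, and its log2 change was -2.97 without refed library A, -3.10 without mated library A and -5.56 without mated library B. Its call was lost against a 2-fold change (adjusted p = 0.0837) and without refed library A (0.0809), refed library B (0.0529) or mated library A (0.107). TTHERM_00655890, chosen after its values were seen, was at 192 ± 72.1 CPM in refed and 699 ± 94.4 CPM in mated cells (log2 change 1.87, SE 0.38, edgeR adjusted p = 0.0143), a call lost against a 2-fold change (adjusted p = 0.0883) and without mated library A (0.056) or B (0.0555).

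With DESeq2 size factors, 4027 of the 4046 higher genes and 3478 of the 3730 lower genes kept their call. With library size alone, all 4046 higher genes and 256 of the 3730 lower genes kept their call, for a split of 7862 higher and 256 lower, and the median log2 change of all genes moved from -0.02 to 0.76. Fitting only the 4 libraries compared gave 5104 higher and 2880 lower, the test against a 2-fold change gave 1486 higher and 115 lower, and the number of genes changed was 3915 without refed library A, 1683 without refed library B, 1592 without mated library A and 3028 without mated library B.

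**Figure D2:**
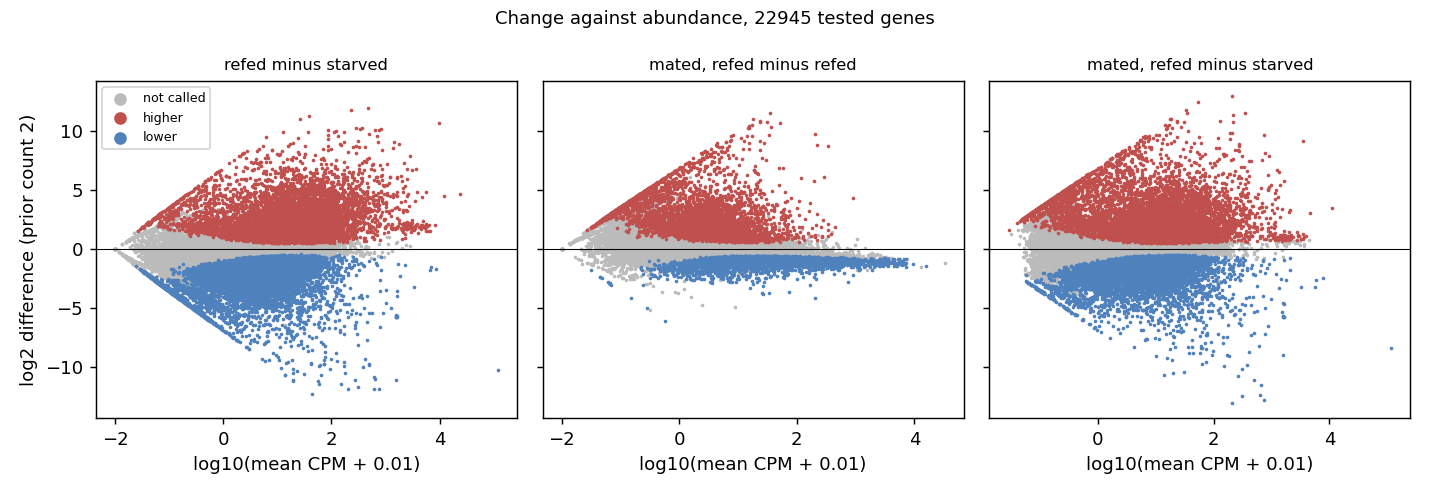
Each panel plots, for 1 comparison, the log2 difference of every tested gene (prior count 2) against the log10 of its mean CPM + 0.01 in the libraries compared, with genes called higher in red, lower in blue and not called in grey. In the comparison of mated with refed cells the median log2 difference went from 0.88 in genes under 1 CPM to -1.05 in genes over 1000 CPM under TMM, and from 1.52 to -0.24 under library size alone, where 256 genes in all were called lower.

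A set of 719 genes had counts in both mated libraries and 0 counts in all 4 non-mating libraries. By comparison, 133 genes had counts only in both starved libraries and 5 only in both refed libraries. Most of the 719 genes were scarce: the median was 0.114 CPM in mated library A and 0.0651 CPM in B, 310 passed the filter for testing, 75 reached a mean of 1 CPM and 14 a mean of 10 CPM. Together they made up 0.144% of the counts in mated library A and 0.0334% in B. A count of 0 in a non-mating library allows up to 0.0419 CPM at the shallowest scaled depth. With all libraries thinned to 1 scaled depth and the sets formed anew, the mated set held 699 genes, and the starved and refed sets 142 and 5. These 699 need not be among the 719, of which 92.9% were still counted in both mated libraries when those were thinned. Without mated library B the set held 1191 genes, with up to 3 counts allowed in each non-mating library 1094, and with at least 10 counts asked in both mated libraries 341. By construction the first and second of these changes can only enlarge the set, and the last can only shrink it.

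**Figure D3:**
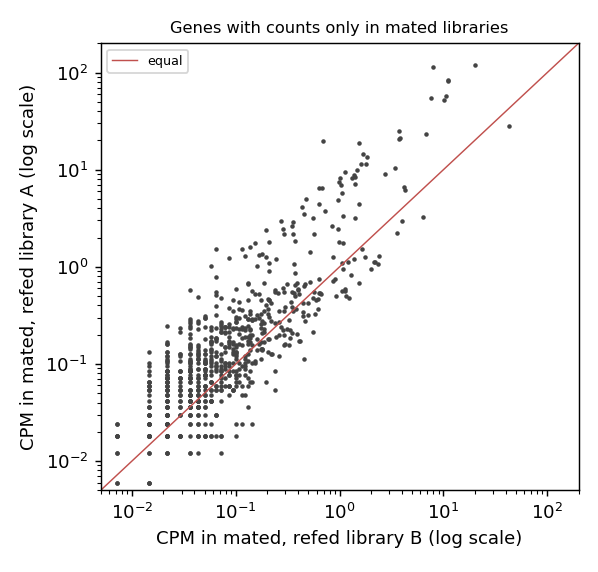
Each point is 1 of the 719 genes counted in both mated libraries and in none of the 4 non-mating libraries, with CPM in mated library A on one axis and in B on the other, both on log scales, and a line where both are equal. Library A was the higher of the pair for 502 genes, and by over 2 times for 292.

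Mated, refed cells differed from starved cells in 58.3% of the genes tested. In this comparison 6951 genes were higher and 6422 lower than in starved cells, and 4710 and 3356 passed the test against a 2-fold change. Genes that had risen on refeeding of non-mating cells made up 81.8% ± 0.98 of the counts of tested genes in mated, refed cells (SD, n = 2), and genes that had fallen 7.19% ± 0.54. The largest rises were TTHERM_000753495, from 0 counts to 105 ± 58.6 CPM (SD, n = 2), at least 4558-fold (edgeR adjusted p = 0.000347), and TTHERM_00237610, at least 3028-fold (edgeR adjusted p = 0.00171). By mated library A alone the first was at least 2761-fold higher, and the second was at least 5186-fold higher by A alone and at least 870-fold by B alone. TTHERM_000703949 fell from 28.1 ± 0.97 CPM to 0 counts in the mated and in the refed libraries, at least 1420-fold (edgeR adjusted p = 3.86e-05). TTHERM_00191070 fell from 406 ± 183 to 0.0311 ± 0.0236 CPM, a ratio of 12247 with a 95% exact counting interval from 6659 to 25539 (edgeR adjusted p = 2.8e-05), and its log2 change of -13.57 became -12.95 without starved library A and -14.67 without mated library A. TTHERM_00655890, chosen after its values were seen, fell by 8.38 on the log2 scale (SE 0.50, edgeR adjusted p = 3.8e-05). With totals that leave out the most abundant gene, the split was 5176 higher and 8591 lower, and the median log2 change of all genes moved from -0.02 to -0.52.

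The genes that responded to refeeding were those that most often differed after mating, in the opposite direction. Of the 7621 genes that fell on refeeding, 2529 (33.2%) were higher in mated than in non-mating refed cells and 380 were lower. Of the 6594 genes that rose on refeeding, 2417 (36.7%) were lower in mated cells under TMM and 238 were higher, and 5.92% of the 2417 stayed lower under library size alone. Independent lists of these sizes would share 1344 and 1072 genes. Such lists take no account of abundance, with which the comparisons ran in opposite directions under TMM. Over 1000 CPM, 149 genes were higher and 19 lower on refeeding, against 0 and 146 after mating. Under 1 CPM these were 618 and 1645, against 1437 and 111. The 684 genes that fell to 0 counts in both refed libraries could not be called lower after mating. Unchanged groups simulated against the same libraries shared at most 1, but they hold almost no calls, so this says little about the shared libraries. Across genes, which are not independent replicates, the refeeding change and the mated-minus-refed difference had r = -0.41, against -0.52 in the simulations, Spearman's rho = -0.50, against -0.48, opposite signs in 69.9% of genes, against 67.1%, and a covariance of -1.55, against -0.135. The same refed libraries enter both differences with opposite signs and were not split between them, so part of the excess may come from them.

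Against starved cells, the mated and non-mating refed cells changed mostly the same genes. There were 5215 genes higher in both and 4929 lower in both, where independent lists would share 1998 and 2133; the simulations, with almost no calls, shared 0. The changes had r = 0.785 across genes, against 0.489 simulated, the same sign in 80.3% of genes, against 66.6%, and a covariance of 4.397, against 0.124. Part of this may come from the shared starved libraries, which enter both changes and were not split between them. In 1443 genes the mated cells were higher than both other groups, where independent lists would share 1226, and in 1121 genes lower than both under TMM, where independent lists would share 1044. The same mated libraries enter both comparisons, so part of these overlaps may come from them. Under library size alone only 256 genes in all were lower in mated than in refed cells.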

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

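The alternative with library totals without the most abundant gene, every alternative for genes counted only in mated cells (other definitions, thinning and left-out libraries), the alternatives for neighbouring genes and the replicate block by column letter were chosen after the data were examined. Of the alternative values, 358 stayed on the same side of their threshold or within 1.5 times of the reported count (correlations and covariances: within 1 SD of the values with a library left out), 44 moved further, 12 calls of named genes were lost and 0 of named genes were reversed. Of the 358, 226 were values of named genes, most of them picked for the largest changes in these same data. The 44 that moved were all counts, correlations or covariances. The 38 planned gene lists had no members, so camera with an estimated correlation, fry and the other list alternatives were not run. The replicate numbers of the labels could not be used as a block, since the deposited columns carry only letters that are not tied to them. With the letter as a replicate block, 6341, 13457 and 12349 genes changed for mated against refed cells, refeeding and mated against starved cells, and TTHERM_00264680 had an adjusted p of 0.0618, the only call of a named gene that this fit lost. Libraries of the same letter deviated together by r = 0.099, -0.028 and 0.023 across genes in the 3 pairs of groups.

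With library size alone, mated against refed cells gave 7862 higher and 256 lower genes and refeeding gave 4307 higher. With totals that leave out the most abundant gene these were 7898, 260 and 3480, and refeeding gave 13400 lower, among them 253 genes reported as higher. Both remove the TMM factors, by construction. At 10 CPM in at least 2 libraries only 10173 genes were tested, which lowers each count: 3518 changed (1917 higher, 1601 lower) for mated against refed cells, 8133 (3927 and 4206) for refeeding and 7478 (3848 and 3630) for mated against starved cells, with a neighbour correlation of 0.173. The test against a 2-fold change asks for more and gave 1601 changed (1486 higher, 115 lower), 9386 changed with 4789 lower for refeeding, and 8066 changed with 3356 lower for mated against starved cells.

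Leaving out 1 library at a time, where the lone sample is assumed to vary like the other groups, mated against refed cells gave 1592 to 8462 genes changed, 1334 to 4768 higher and 222 to 4398 lower; fewer samples lower the power, and no other cause was tested. The correlation of the mated-minus-refed difference with the refeeding change ran from -0.46 to -0.37, its covariance from -1.95 to -1.34, and the neighbour correlation from 0.196 to 0.207. Genes counted only in mated cells numbered 787 to 1191 with a library left out, 1094 with up to 3 counts allowed elsewhere and 341 with at least 10 counts in both mated libraries. Leaving out a library or allowing counts elsewhere can only enlarge the set of 719, and asking for more counts can only shrink it. Depth limits the scarce genes: 1 count is 0.0060 to 0.0140 CPM.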

Other observations

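The tests of whole scaffolds (shuffles and rotations), of the scaling of genes that rose on refeeding and of the gap between genes that fell and rose, and the split of the mated-only genes by abundance, were chosen after the results were seen.

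Genes that are neighbours in the reference assembly (JCVI-TTA1-2.2) changed alike. Across 19452 adjacent pairs, the mated-minus-refed change of a gene and that of its neighbour had r = 0.199, above the highest of 1000 shuffles (0.0244; permutation p = 0.001, the smallest they can give), and r fell to 0.115 at 2 genes apart and was 0.050 at 20 genes apart. For refeeding, r was 0.162 for neighbours and 0.0098 at 20 genes apart. Differences between the 2 libraries of a group also went with position, with r = 0.165, 0.0873 and 0.123 between neighbours in starved, refed and mated cells. Over 228 scaffolds with at least 20 tested genes, 6.65% of the variance of the mated-minus-refed change lay between scaffolds, against at most 1.46% in shuffles and 2.73%, 2.24% and 2.71% for the difference between the 2 libraries of the starved, refed and mated groups. For refeeding the share was 2.32% (at most 1.47% in shuffles), and for mated against starved cells 3.59% (at most 1.42%). Each share is of its own total variance, and the totals were unlike, so like shares are not like amounts. The median absolute log2 difference was 0.355, 0.240 and 0.290 between the 2 libraries of the starved, refed and mated groups. Between starved and refed libraries it was 1.34 to 1.45. Runs of at least 4 consecutive genes changed at least 2-fold in the same direction held 190 genes in the mated against refed comparison (at most 93 in shuffles), 1195 on refeeding (at most 751) and 1018 for mated against starved cells (at most 500).

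The 75 mated-only genes with a mean of at least 1 CPM were uneven between the mated libraries. Library A was higher for 59 of them and over 4 times higher for 44, and B was higher for 16.

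As to the opposite signs of the refeeding change and the mated-minus-refed difference, starved-like cells left among the mated cells would bring the abundant transcripts of starved cells with them. The 20 most abundant genes that fell on refeeding imply a median share of 1.07% of such RNA (quartiles 0.199% and 2.35%). The 2529 genes that fell and were higher after mating need a median of 66.0% (quartiles 35.4% and 111.7%). The 2417 genes that rose and were lower after mating need a smaller median of 21.2%, with quartiles of 1.71% and 42.6%. Under library size alone 100% of the genes that fell on refeeding and were higher after mating stayed higher, and 5.92% of those that rose and were lower stayed lower, but this scaling moves all genes of the comparison upward, so neither share, whatever was predicted of it, decides which group is due to scaling. A single factor per library cannot make the gap between genes with the lowest and the highest refeeding change, whose median mated-minus-refed differences lay 1.40 apart on the log2 scale, against at most 0.463 in the simulations. Spread between libraries of a group, shared through the refed libraries, is argued against as the whole source by the covariance of -1.55, where the simulations reached -0.141. Ranks and signs, however, lay near the simulated values. The simulated groups were unchanged and varied only by the spread within groups. A deviation common to both refed libraries would enter both differences with opposite signs, and neither the covariance nor the gap can exclude it. The trends of both changes with abundance, which ran in opposite directions, were not removed from the covariance or the gap, so their part stays open. Which of the groups differed in absolute level stays open, as does a difference between mated and vegetative cells in the response to food, which was not tested.

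Genes counted only in the mated libraries may reflect mating, but strain CU427 entered those libraries alone, and with 0 non-mating libraries of that strain the second strain and mating cannot be told apart. Deeper sequencing is argued against by thinning, after which 92.9% of the genes were still counted in both mated libraries. Genomic DNA would cover genes about evenly, whereas counts per kb spanned 34.9 times between the 10th and 90th percentiles in mated library B and 46.3 times in A. This argues against even coverage as the source of the whole set. Most of the span lay above the median: the 10th percentile, median and 90th percentile were 2.20, 8.33 and 76.9 in B and 3.85, 16.2 and 178 in A. A low even background beneath some transcribed genes would also give a wide span, so the test cannot decide for the scarce genes. On 2 scaffolds most of the counted genes belonged to this set (7 of 8 and 4 of 5 genes, with 0 counts from these scaffolds in the non-mating libraries), where shuffles gave at most 1 such scaffold but rotations that keep neighbours together gave up to 2 (6 of 1000), so sequence present in the mated pool alone and neighbours that change alike both stay open for those few genes.

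The likeness of neighbouring genes may also have technical sources. Reads assigned across gene borders would act over short gaps, but pairs over 1000 bases apart had r = 0.203. Reads shared between tandem copies would act on genes of similar length, but pairs whose lengths differ by over 1.5 times had r = 0.154. For these pairs r was 0.108 on refeeding, against 0.162 for all neighbours, and 0.108 for mated against starved cells, against 0.185. The longest run lower after mating held 5 genes of 801 to 864 bases, and the longest higher run 6 genes of 576 to 4456 bases. Shuffles gave a run of up to 8 genes in this comparison, so neither run was longer than shuffled positions can give. Gene length is only a stand-in for similar sequence, so shared reads stay open for a part of the likeness. The trend of the change with abundance was removed and left 7.70% of the variance between scaffolds. Because neighbours also went together between libraries of 1 group, a part of the likeness is not specific to mating or food, and its source was not tested.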
